A study of Mus musculus with 4 samples.

How the data were processed

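RNA was measured in H460 cells, an established human lung carcinoma line, after 4 h with 250 µM farnesol or with the vehicle dimethyl sulphoxide. The samples' organism label names the mouse, but the labels' protocols name the human line and the probes carry human gene names, so the data were treated as human. Per the labels, there were duplicate experiments, each with a farnesol RNA and its matched vehicle RNA, and each pair of RNAs was hybridised on 2 arrays with the dyes exchanged. The 4 arrays therefore hold 2 replicates, and the arrays of a pair are technical repeats. Per the labels' protocols, total RNA was amplified and labelled with Cy3 or Cy5 by a linear amplification kit, and both labelled RNAs were hybridised together on oligonucleotide arrays.

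Each array's scan was read with Agilent Feature Extraction, version 8.1.1.1 per the file headers and 8.1 per the labels. Per the file headers, the deposited intensity values were the mean brightness of a spot and the median brightness of its local background in each channel, without correction. The deposited processed intensity values were background-subtracted with spatial detrending and dye-normalized by a linear step and LOWESS, per the file headers. The deposited log10 ratio of Cy5 over Cy3 came from those processed values, per the file headers. Other deposited columns were flags of the scanner software for spots well above background, saturated or outlying, per the file headers. The authors also deposited a table with a linear ratio of farnesol over vehicle and a p-value per probe, whose headers name no program. Both deposited copies of this table held identical values, so it gave no second replicate. Its log2 ratio followed the scanner software's mean log ratio of the replicate 1 arrays (r 0.9999 across probes), with the dyes turned as the labels give them, and this bears on the direction of all ratios.

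The computation started from the scanner intensities, in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. Background was corrected by normexp with an offset of 50, and log ratios were normalized by loess within each array, with control and outlying spots at weight 0. Controls and outlying spots were then left out and saturated spots were kept. The sign of arrays with farnesol in Cy3 was turned, spots of 1 probe were averaged, and the arrays of a pair were averaged, so that n = 2. Values are log2 ratios of farnesol over vehicle, and SD is the spread of the 2 replicates. The offset shrinks the ratios of dim probes.

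A probe was tested where it was well above background in the same condition's channel on at least 1 array of each replicate. The brightest probe stood for a gene. This left 28598 features, of which 17872 had a gene symbol and 10726 did not, and 6572 genes had more than 1 tested probe. Only SFRS10 had probes at least 2-fold higher and at least 2-fold lower (log2 ratios -1.005 and 1.74). Gene names are those of the array's design and can be old. The reference table supplied was of the mouse and was not used here, and no gene position is given.

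The test was limma's moderated test of the mean of the 2 replicates against 0, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. It has 1 residual degree of freedom per gene, to which moderation added 1.81. Beside it, genes were counted whose ratio was at least 2-fold the same way in both replicates, with all 4 arrays in that direction. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 27 lists. At this preset its p-value treats a list's members as nearly independent and does not measure the spread between the 2 replicates. Each list's median was also ranked among 10000 random lists of the same size and intensity, and fry and camera with an estimated correlation were run beside it. The estimated correlation rests on the single difference between the replicates. Values with no test across replicates were given 95% intervals over genes by 10000 bootstrap draws, and genes are not independent.

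The lists covered ER chaperones, ER-associated degradation, sensors of the unfolded protein response, ATF4 and CHOP targets, amino acid synthesis and transport, and aminoacyl-tRNA synthetases. They also covered cholesterol synthesis and uptake, PPAR, FXR and LXR targets, heat shock proteins, NRF2 targets, immediate early genes and MAP kinase phosphatases. Further lists held NF-kappaB targets and cytokines, p53 targets, pro-apoptotic genes, anti-apoptotic genes, G1/S genes, mitosis, hypoxia, metallothioneins and autophagy. The rest held interferon-stimulated genes, oxidative phosphorylation, ribosomal proteins, and markers of leukocytes, fibroblasts and endothelium. Of 485 fixed members, 481 were on the array and 477 were tested, 11 of them matched through older names added once the array's names were seen. HSPA1B, AKR1C2, GINS1 and ANKRD37 were not matched by name, and FABP1, CD3D, PDGFRB and POSTN were not tested.

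The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took 12 genes whatever their values, and a few genes it names are not reported here. It also took the 10 genes with the largest rise and the 10 with the largest fall, filled by size among genes at least 2-fold changed in both replicates where too few passed, and well above background in both channels on all 4 arrays. From each list it took up to 4 members past the threshold or, where fewer than 2 passed, the 2 largest. Genes named outside the rule were chosen after their values were seen. These are list members beside the rule's, and the genes first named in the closing section.

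The procedure was tested on simulated data with 28598 features and gene variances drawn from the prior fitted here. Of 50 genes each with a true log2 change of 1, 2, 4 and 6, the test called 6, 39, 49 and 48, and the sign was right for all. Beside those true calls it called 12 of 28378 unchanged features, so false calls were not a negligible part of all its calls. Measured sizes were smaller than the true ones, with medians of 0.78, 1.63, 2.87 and 4.42. A changed gene's variance was drawn like that of any other gene. In the real data, named genes at least 2-fold higher in both replicates had a median SD of 0.43, against 0.09 over all named genes. The simulated call rates, for the test and for the count by size, may therefore be too high for such genes. A list shifted as a whole reached adjusted p = 2.63e-18 by camera, and 0 of 20 unshifted lists passed (camera). Noise was drawn independently for each gene, so this could not show how camera treats lists whose members vary together. With an estimated correlation the shifted list had adjusted p = 0.993, so that variant missed this simulated shift. A single list was shifted, by less than the smallest gene change simulated, so how the variant treats larger shifts was not shown.

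The 4 arrays were on 4 slides and scanned on 1 day, so that neither slide nor day could be tested as a batch. Alternatives covered the background correction, the scanner software's processed values, median centring, quantile normalization of the mean intensities, the filter on dim probes, the probe rule, the dye orientation, the model and the replicate left out. The planned limma test on the authors' deposited table was not run, because its copies were identical. The planned fit of 4 arrays with a dye term and a random pair could not be run, because 4 arrays do not allow that correlation to be estimated beside the dye term.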

Results

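Farnesol, an isoprenoid alcohol derived from an intermediate of the mevalonate pathway, was given to H460 lung carcinoma cells at 250 µM for 4 h. The RNA was compared with that of vehicle-treated cells on 2-colour arrays of 41000 probes. Replicate 1 and replicate 2 are duplicate experiments, each measured on 2 arrays with the dyes exchanged. Between 82.7% and 93.0% of the probe spots were well above background in a channel, and 19 to 51 spots per channel were saturated. The dye-swapped arrays of a pair correlated across genes at r = 0.943 in replicate 1 and 0.942 in replicate 2, against 0.633 to 0.684 for arrays of different replicates. The replicates' mean log2 ratios correlated at r = 0.680 (Spearman's rho 0.464) across genes, which are not independent, and 65.5% of features had the same sign in both. Among the 445 features with a mean change of at least 2-fold, 100% had the same sign, but a choice by the mean of the same 2 replicates favours this. The number of replicates, 2, limits the precision of every value below.

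The comparison asked which transcripts differ after 4 h of farnesol, in a study of apoptosis and the endoplasmic reticulum (ER) stress response. EGR1, a zinc finger transcription factor of the early growth response, rose 262-fold (log2 ratio 8.03 ± 0.08, SD, n = 2). Over 10 other settings of the processing its log2 ratio ran from 7.80 to 8.70, a wider range than its SD. JUN, a subunit of the AP-1 transcription factor, rose 103-fold (6.69 ± 0.07), with its farnesol spots saturated on 2 of the 4 arrays. NR4A1, an orphan nuclear receptor, rose 67.4-fold (6.07 ± 0.02), although its second, dimmer probe had a log2 ratio of 0.25 and the mean of its probes, 3.16, did not pass (adjusted p = 0.0763). All 3 genes had limma adjusted p = 0.0342 and were higher on 4 of 4 arrays. No other named gene passed. Other large log2 ratios, none of which passed, were those of ATF3 (7.09 ± 0.42), a stress-induced repressor of the ATF family, IL8 (6.89 ± 0.67), a neutrophil chemokine, FOS (6.76 ± 0.30), the partner of JUN, EGR2 (6.44 ± 0.49), EGR4 (6.13 ± 0.16) and CXCL2 (5.71 ± 0.78), another chemokine. Their adjusted p ran from 0.0663 for EGR4 to 0.192 for CXCL2, and a second probe of ATF3 gave 2.90. Over the other settings IL8 ran from 6.67 to 7.73, FOS from 6.54 to 7.57 and EGR2 from 6.24 to 7.58.

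Counted by size, 206 named genes were at least 2-fold different the same way in both replicates, 150 higher and 56 lower with farnesol. With median centring in place of loess the same count was 124 higher and 109 lower. Over all features, with or without a symbol, the main count was 256. In simulated data, also over all features, this rule took 43 of 28378 unchanged features. It took 1, 42, 50 and 50 of 50 genes with a true log2 change of 1, 2, 4 and 6. The simulated spread was drawn as for all features, while these 206 genes had a median SD of 0.38. Of the 150 higher genes 74.7%, and of the 56 lower ones 83.9%, had the larger change in replicate 1. The 150 higher genes had a median log2 ratio of 2.07, and 17 of them were at least 16-fold higher in both replicates. The 56 lower genes had a median of -1.33, and none reached 4-fold in both replicates. The largest lower values were those of RPA1 (-2.30 ± 0.57, 4.92-fold), a subunit of the single-stranded DNA binding complex, TM9SF2 (-2.25 ± 0.69), SFRS1 (-2.12 ± 0.45), a splicing factor, and PARP1 (-2.09 ± 0.37), which adds poly(ADP-ribose) at DNA breaks. A second SFRS1 probe gave -0.45, and the mean of its probes was -1.28. A second TM9SF2 probe gave -1.40. DKFZP564O0463 (-1.97), PRSS11 (-1.96), a secreted serine protease, MAEA (-1.88), the mitochondrially encoded MTND6 (-1.87), ARL6IP5 (-1.77) and TFB2M (-1.68), a mitochondrial transcription factor, came next. The other probes of MAEA gave -1.39 and -0.65. Limma called 0 genes lower, where the lowest adjusted p was 0.190, and 3043 named genes (17.0%) had an unadjusted p under 0.05, 715 higher and 2328 lower. The count past the threshold depended on processing and model, with 55 genes at a normexp offset of 0 and 51 from the scanner software's processed values.

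**Figure D1:**
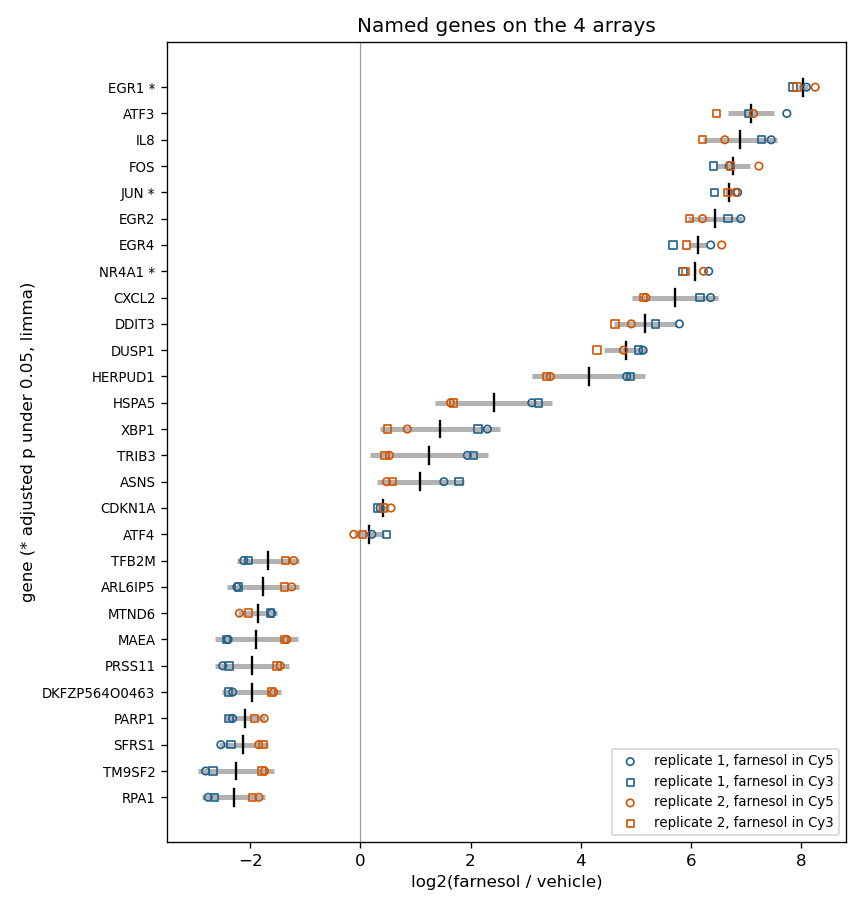
Log2 ratio of farnesol over vehicle (x axis) of named genes on each of the 4 arrays, with colour for the replicate and shape for the dye, the black tick at the mean and the grey bar 1 SD of the 2 replicates to each side. EGR1, JUN and NR4A1, marked by a star, passed limma's test, and EGR1 reached 8.03, while RPA1 stood at -2.30.

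Immediate early genes, switched on within minutes to hours of a stimulus and mostly encoding transcription factors, rose as a list, with a median log2 ratio of 3.42 (camera, adjusted p = 9.83e-30; adjusted p = 0.701 with an estimated correlation). All 23 members were higher in both replicates, and the replicate medians were 3.68 and 3.25. Of these, 22 passed adjusted over the list alone, against 3 over all genes, and 18 were at least 2-fold higher in both replicates. IER2 (4.62 ± 0.44), IER3 (3.96 ± 0.995), FOSB (2.94 ± 0.04) and MYC (1.51 ± 0.03) were among them. MAP kinase phosphatases and feedback inhibitors rose too, with a median of 1.17 over 15 members (adjusted p = 8.99e-08; adjusted p = 0.701 with an estimated correlation). The replicate medians were 1.83 and 0.53, and the median was 0.73 with the mean of a gene's probes. Of the members, 10 passed adjusted over the list alone, all higher, and 0 by limma over all genes. DUSP1, which removes phosphate from JNK, p38 and ERK, had a ratio of 4.81 ± 0.39, or 28.1-fold. MIG-6, an inhibitor of the EGF receptor, had 4.08 ± 1.69, with 0.89 from its other probe and 2.48 as the mean of both. NF-kappaB targets and cytokines rose with a median of 1.74 over 22 members, all higher in both replicates (adjusted p = 4.98e-12; adjusted p = 0.701 with an estimated correlation). The replicate medians were 2.30 and 1.07. Of the members, 11 passed adjusted over the list alone and 0 by limma over all genes, with CXCL1 (4.45 ± 0.27) and NFKBIA (4.01 ± 0.70), the inhibitor of NF-kappaB, beside IL8 and CXCL2.

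Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose with a median log2 ratio of 1.16 over 21 members (camera, adjusted p = 3.52e-09; adjusted p = 0.701 with an estimated correlation). Its median was 1.53 in replicate 1 and 0.51 in replicate 2. Of the members, 18 were higher in both replicates, 10 were higher and 1 lower adjusted over the list alone, and 0 passed limma's test over all genes. DDIT3, which encodes CHOP, had a log2 ratio of 5.17 ± 0.57 (36.0-fold, adjusted p = 0.192). GDF15 (2.99 ± 1.19), a secreted stress cytokine, and GADD45A (2.71 ± 0.74), a growth arrest gene, followed. TRIB3, a pseudokinase induced by CHOP, had 1.24 ± 1.07, and TNFRSF10B, a death receptor for TRAIL, had 1.16 ± 0.92. The other probe of TRIB3 gave 0.65. ATF4 itself, which is controlled mainly at translation, had 0.15 ± 0.27, and -0.04 under median centring.

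ER chaperones and folding enzymes rose with a median of 0.31 over 21 members (camera, adjusted p = 0.000601; adjusted p = 0.751 with an estimated correlation). None passed limma's test, over all genes or adjusted over the list alone, and 13 were higher in both replicates. The list's median was 0.35 in replicate 1 and 0.06 in replicate 2, and over both it was 0.08 under median centring (adjusted p = 0.0237) and 0.20 with the mean of a gene's probes (adjusted p = 0.00201). HSPA5, the main ER chaperone BiP, had a ratio of 2.42 ± 1.07 (5.35-fold, adjusted p = 0.237), with 3.17 in replicate 1 and 1.66 in replicate 2. TRA1, the ER chaperone GRP94, had 2.01 ± 0.94, with its farnesol spot saturated on 1 array. ER-associated degradation genes fell by camera's test (adjusted p = 0.0256; adjusted p = 0.701 with an estimated correlation), with a median of -0.18 but a mean of 0.07 over 18 members and replicate medians of -0.06 and -0.34. Under median centring the median was -0.36. HERPUD1 (4.14 ± 1.03, 17.6-fold, its farnesol spot saturated on 1 array), a ubiquitin-like ER membrane protein, and SEL1L (0.88 ± 0.43), a ligase cofactor, were higher adjusted over the list alone. The other probe of SEL1L gave -0.01, and the mean of its probes 0.43. VCP (-0.64 ± 0.12), the ATPase that extracts substrates, and DERL1 (-0.34 ± 0.01) were among the 6 lower ones. This list's call was lost under 4 of 10 other settings of the processing. Sensors and transcription factors of the unfolded protein response did not pass (median 0.15, adjusted p = 0.261; replicate medians 0.16 and -0.00; -0.04 under median centring), with 0 of 13 members past limma's threshold. XBP1, whose spliced form is a factor of the response, had 1.44 ± 1.09, with 0.84 from its other probe, and NFE2L2 had 0.87 ± 1.23, with 1.74 in replicate 1, -0.00 in replicate 2, -0.13 from its other probe and 0.37 as the mean of both.

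Amino acid synthesis and transport genes did not pass as a list (median -0.20, adjusted p = 0.267), and the median was 0.01 in replicate 1, -0.31 in replicate 2 and -0.37 under median centring. SLC38A2, a neutral amino acid transporter, had 1.39 ± 1.30 and ASNS, asparagine synthetase, 1.09 ± 0.80, while PSAT1, of serine synthesis, had -1.21 ± 0.14 and alone passed adjusted over the list alone. The other probe of ASNS gave -0.00, and the mean of its probes 0.54. For SLC38A2 the other probes gave 1.04 and 0.40. Aminoacyl-tRNA synthetases did not pass (median -0.08, adjusted p = 0.123), with replicate medians of 0.01 and -0.22, NARS at -0.87 ± 0.39 and RARS at -0.76 ± 0.18. Under median centring the list passed (median -0.21, adjusted p = 0.0397). Genes of cholesterol synthesis and uptake did not pass either (camera, adjusted p = 0.658), and their median of -0.05 and the direction of the test were negative while the mean was 0.14. Of 24 members, 4 were higher and 4 lower adjusted over the list alone. Of the higher ones, HMGCS1 had 1.79 ± 0.68 (3.45-fold), INSIG1 1.52 ± 0.05 and IDI1 1.16 ± 0.18. EBP (-0.56 ± 0.01), SQLE (-0.53 ± 0.08) and FDPS (-0.47 ± 0.06), which makes farnesyl pyrophosphate, were among the lower ones. Targets of PPAR, FXR and LXR had a median of 0.03 (adjusted p = 0.0608; 0.07 with offset 0, adjusted p = 0.0451), with ADFP, a lipid droplet protein, at 1.46 ± 0.69 and MYLIP, a ubiquitin ligase, at 1.41 ± 1.06 (2.39 with processed values).

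Heat shock proteins rose with a median of 0.61 over 18 members (camera, adjusted p = 0.00404; adjusted p = 0.751 with an estimated correlation). The list's median was 0.09 in replicate 1 and 1.07 in replicate 2. DNAJB1, an HSP40 co-chaperone, had 2.96 ± 0.22 and HSPA8, the constitutive HSC70, 0.69 ± 0.06, and these 2 passed adjusted over the list alone. HSPA6, an inducible HSP70, had 0.24 in replicate 1 and 4.36 in replicate 2 (2.30 ± 2.91, adjusted p = 0.518). Metallothioneins, which bind zinc and copper, rose with a median of 0.81 (adjusted p = 0.00021; adjusted p = 0.701 with an estimated correlation), and all 10 members were higher in both replicates, with MT1X at 1.11 ± 0.64 and MT2A at 1.09 ± 0.69. Their median was 1.16 in replicate 1 and 0.46 in replicate 2, and none passed limma's test adjusted over the list alone. Interferon-stimulated genes rose by camera's test (adjusted p = 0.00404; adjusted p = 0.701 with an estimated correlation), with a median of 0.12, a mean of 0.72 and replicate medians of 0.07 and 0.17. The median was 0.28 with offset 0 and 0.27 with processed values. Of 13 members, 6 were higher and 1 lower adjusted over the list alone, and IFIT2 (2.74 ± 1.04) and IFIT1 (2.37 ± 0.93), which bind viral RNA, led. NRF2 targets, the antioxidant genes, fell with a median of -0.36 over 20 members (adjusted p = 8.94e-07; adjusted p = 0.701 with an estimated correlation). The replicate medians were -0.18 and -0.57, and median centring gave -0.56. Of the members, 16 were lower in both replicates and 4 passed adjusted over the list alone, among them HMOX1 (-0.75 ± 0.25), heme oxygenase, and AKR1C1 (-0.74 ± 0.01).

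**Figure D2:**
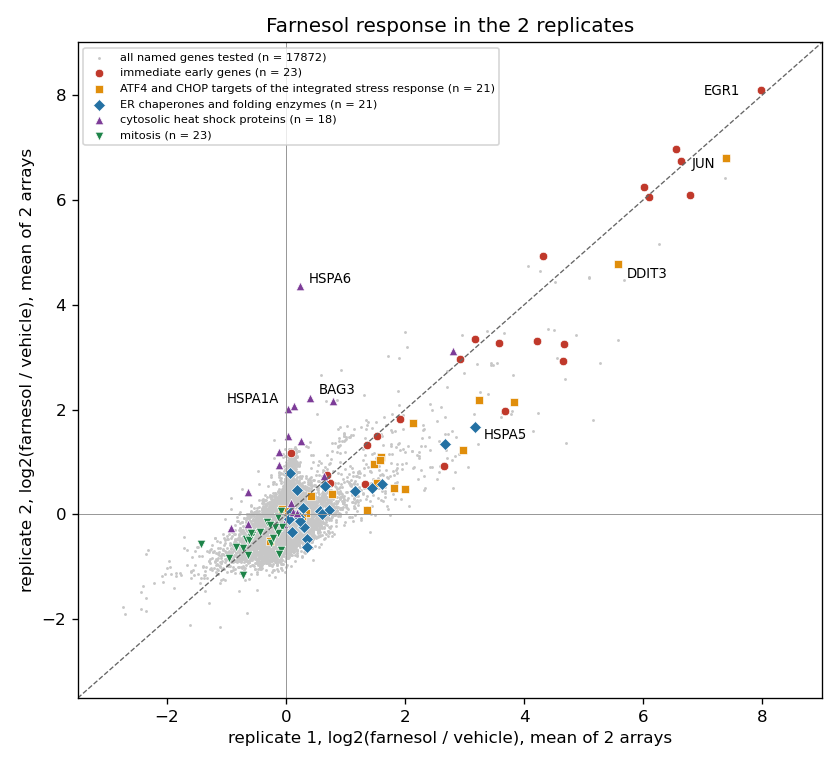
Mean log2 ratio of farnesol over vehicle of each named gene in replicate 1 (x axis) and replicate 2 (y axis), with members of 5 lists coloured, ATF3 shown with the ATF4 and CHOP targets although it is also an immediate early gene, and equal values on the dashed line. EGR1 lay at 7.97 and 8.09, HSPA5 below the line at 3.17 and 1.66, and HSPA6 above it at 0.24 and 4.36.

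Genes of mitosis fell with a median log2 ratio of -0.43 over 23 members (camera, adjusted p = 1.15e-11; adjusted p = 0.701 with an estimated correlation). Of these, 22 were lower in both replicates and 11 passed adjusted over the list alone. The largest values were those of PLK1 (-0.998 ± 0.62; -0.31 from its other probe and -0.65 as the mean of both), a mitotic kinase, TOP2A (-0.94 ± 0.30), which untangles DNA, and CCNB2 (-0.90 ± 0.09), a cyclin. G1/S and DNA replication genes fell with a median of -0.31 over 27 members, 22 of them lower in both replicates (adjusted p = 1.39e-07; adjusted p = 0.701 with an estimated correlation). The replicate medians were -0.20 and -0.46, and none passed limma's test adjusted over the list alone, with PCNA, the polymerase clamp, at -0.98 ± 0.18 and MCM3, a helicase subunit, at -0.69 ± 0.24. Genes of oxidative phosphorylation fell with a median of -0.33 over 20 members, 16 of them lower in both replicates (adjusted p = 1.5e-06; adjusted p = 0.701 with an estimated correlation). NDUFA9, of complex I, had -1.11 ± 0.14 and ATP5A1, of the ATP synthase, -0.98 ± 0.00, and 8 members passed adjusted over the list alone. Median centring gave -0.47 for G1/S and -0.55 for oxidative phosphorylation. Over all genes, limma called 0 members of these lists.

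Genes of cell death and growth arrest had values in both directions. Pro-apoptotic genes (median 0.04, adjusted p = 0.459), anti-apoptotic genes (0.12, adjusted p = 0.658) and p53 targets (0.01, adjusted p = 0.518) did not pass camera's test. The replicate medians were 0.08 and -0.05 for anti-apoptotic genes and 0.11 and -0.05 for p53 targets. Median centring gave -0.03 for pro-apoptotic genes, 0.07 for anti-apoptotic genes and -0.02 for p53 targets. Adjusted over the list alone, 3 of 18 p53 targets were higher (GADD45A, BTG2 and PLK3) and 0 lower. PMAIP1, the BH3-only protein NOXA, had 2.22 ± 0.32 and was the only pro-apoptotic member of 20 past the threshold adjusted over the list alone. MCL1, which NOXA binds, had 2.53 ± 0.88 and BIRC3, an inhibitor of apoptosis, 2.03 ± 1.24 (3.72 with processed values). Of the anti-apoptotic list, MCL1 was higher and BIRC5 (-0.70 ± 0.09) lower adjusted over the list alone. CDKN1A, the p53-induced cell cycle inhibitor p21, had 0.42 ± 0.10 (adjusted p = 0.221), with 0.15 from its other probe and 0.21 under median centring, and PLK3, another p53 target, 1.97 ± 0.49. Hypoxia and glycolysis genes had a median of -0.03 but a mean of 0.02 (adjusted p = 0.459), with ADM, adrenomedullin, at 2.44 ± 0.76 and LDHA, lactate dehydrogenase, at -0.67 ± 0.28. Autophagy genes had a median of -0.07 (replicates, 0.05 and -0.20) but a mean of 0.08 (adjusted p = 0.773), with MAP1LC3B, an LC3 protein, at 1.46 ± 0.45 and GABARAPL1 at 0.70 ± 0.28 (0.19 from its other probe and 0.44 as the mean of both).

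Ribosomal proteins had a median of 0.01, while their mean of -0.01 and the direction of the test were negative (camera, adjusted p = 0.994). Their replicate medians were -0.04 and 0.03, and under median centring their median was -0.18 (adjusted p = 0.00158). RPL6 had -0.29 ± 0.03 (-0.48 under median centring), and RPS2 was saturated in both conditions on all 4 arrays, so that no fold is given. Markers of other cell types did not pass. Leukocyte markers had a median of 0.07 (adjusted p = 0.110; LCP1 0.57 ± 0.66, CD14 0.15 ± 0.08), and under median centring LCP1 had 0.36 and CD14 -0.00. Fibroblast markers had 0.11 (adjusted p = 0.102; median centring, adjusted p = 0.0334), with THY1 at 0.46 ± 0.54 (0.24 under median centring) and COL1A1 at 0.31 ± 0.06. Endothelial markers had 0.01 (adjusted p = 0.773; replicate medians -0.03 and -0.01), with VWF at 0.16 ± 0.09 (0.09 to 0.25 over the settings) and ENG at -0.05 ± 0.04 (-0.10 to -0.02).

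Across the 27 lists, 13 passed camera's test, 8 up and 5 down, and 6 medians lay above and 2 below those of all 10000 random lists. With an estimated correlation camera called 0 lists, at an unadjusted p under 0.05 also 0, and the lowest adjusted p was 0.701. That correlation ran from -0.07 for fibroblast markers to 1 for MAP kinase phosphatases, and it was 0.004 for immediate early genes. By fry's directional test 0 passed, with 4 at an unadjusted p under 0.05. By fry's mixed test 4 passed, namely immediate early genes, anti-apoptotic genes, ER-associated degradation and oxidative phosphorylation.

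**Figure D3:**
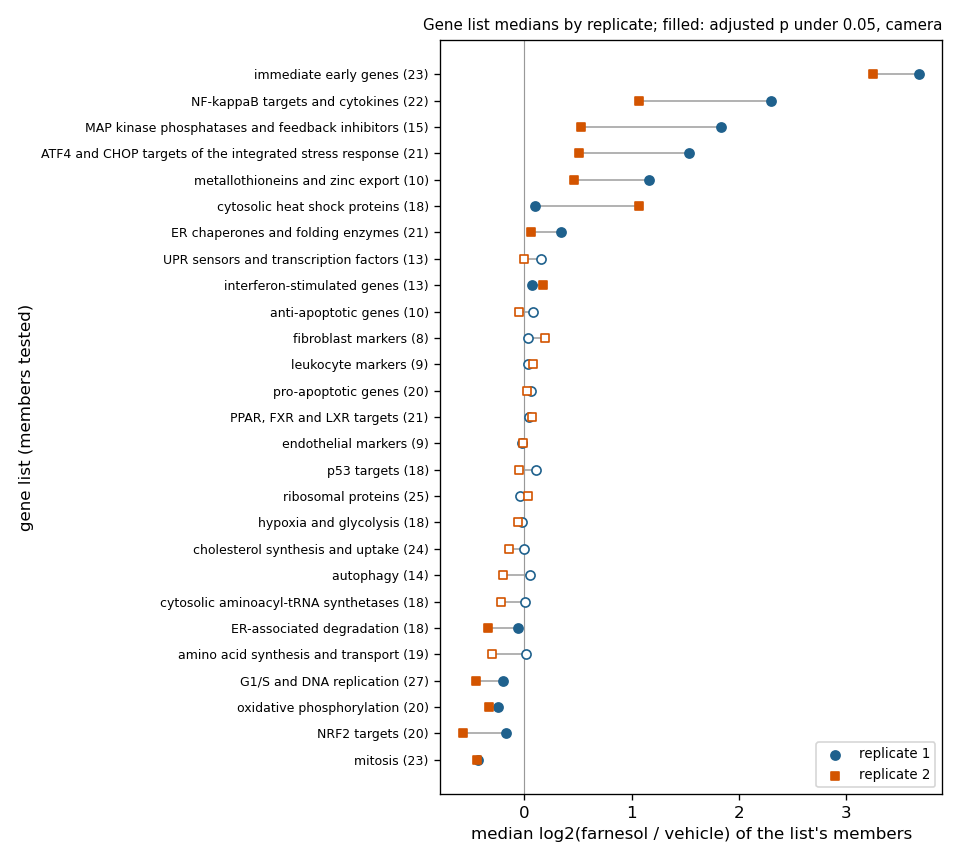
Median log2 ratio of farnesol over vehicle (x axis) of the members of each of 27 gene lists, with circles for replicate 1, squares for replicate 2, filled where the list passed camera's test over both replicates, and tested members in brackets. Immediate early genes stood at 3.68 and 3.25, heat shock proteins at 0.09 and 1.07, and mitosis genes at -0.43 and -0.44.

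The authors' deposited table listed 7018 probes with a p-value of at most 0.001, 2963 with a ratio above 1 and 4055 below. In the authors' deposited table, 873 ratios were at least 2 and 404 at most 0.5, and the ratio was 365 for EGR1, 275 for IL8, 58.9 for DDIT3 and 9.77 for HSPA5. The authors' deposited table described replicate 1, since its log2 ratios correlated across probes at 0.970 with replicate 1 as normalized here. In replicate 2, 82.0% of the probes of the authors' deposited table had the same sign, 68.5% of those with a ratio above 1 and 91.9% of those below, and 95.1% of its probes that were at least 2-fold. For the latter, the median ratio of the replicate 2 to the replicate 1 log2 value was 0.534, with the authors' deposited table used only to choose the probes. That choice rests on their size in replicate 1, which by itself favours smaller values in replicate 2. Without it, 457 named genes were at least 2-fold different in replicate 1 and 455 in replicate 2. A dye effect was tested as the part of the log ratio that did not turn with the dyes. Of 28552 features, 2874 passed limma's threshold for it, with a median absolute size of 0.03 and a largest of 0.54 on the log2 scale, and it cancels in the mean of each pair.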

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

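The fit of 4 arrays without a dye term was chosen only after the data were seen. Against 3 genes past the threshold, normexp with offset 0 gave 55 and the scanner software's processed values 51, each with PCYOX1 as the only lower gene (-2.43 and -2.60). Median centring gave 23, trend and robust moderation 17, only the arrays with farnesol in Cy3 14, and only those with farnesol in Cy5 5 (EGR1, JUN, NR4A1, EGR4 and SAT). The cause was not tested. Each ratio is paired within its replicate, and the fit with no replicate block, on levels per channel, gave 15. Taking the 4 arrays as units gave 1961 as independent with a dye term (419 higher, 1542 lower). It gave 2255 with the pair as a random block and no dye term (520 higher, 1735 lower). These 2 fits differ in both choices, and both count technical arrays toward the degrees of freedom by construction. EGR1 and JUN passed in 10 of 10 settings of the processing, and NR4A1 in 9, losing its call when its probes were averaged (3.16, adjusted p = 0.0763). EGR4 passed in 5, ATF3 and FOS in 4, and DDIT3 in 2. No other setting ended a call among 73 named genes, and the 3 whose sign turned, ATF4 and CD14 among them, had not passed, nor had those whose sign turned with 1 replicate left out, among them ATF4 and NFE2L2.

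The 206 genes at least 2-fold in both replicates became 332 with processed values, and 455 to 457 with 1 replicate left out, which asks for 1 replicate in place of 2. A single replicate leaves no residual degree of freedom, so no test was possible. The 13 lists past the threshold became 0 by camera with an estimated correlation, 0 by fry's directional test and 4 by its mixed test, and 12 to 16 otherwise. Of 270 list values under other settings, 262 kept their side of the threshold. ER-associated degradation lost its call in 4 (adjusted p 0.0698 to 0.124). Aminoacyl-tRNA synthetases and fibroblast markers (median centring, adjusted p = 0.0397 and 0.0334) and PPAR, FXR and LXR targets (offset 0, 0.0451) passed. Apart from calls, 8 of the 270 values changed sign, in 5 lists that had not passed (UPR sensors, p53 targets, pro-apoptotic genes, ribosomal proteins and endothelial markers), and only ribosomal proteins gained a call, turning to -0.18 under median centring (adjusted p = 0.00158). With 1 replicate left out, 9 of 54 list medians changed sign, in 8 lists that had not passed, and 10 moved by at least the spread. The correlation of the replicates was 0.637 with processed values. The dye effect count was 4844 with median centring and 0 by limma with processed values, with 4395 features at an unadjusted p under 0.05. For these the cause was not tested. Probes near background limit ratios, since the offset shrinks them.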

Other observations

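The gene families in this part and its tests were chosen only after the result was seen, except the tests of vehicle levels and of unsaturated immediate early genes. Histone genes, which encode the proteins that package DNA, had a median log2 ratio of 1.19 over 62 members, and 57 were higher in both replicates and 25 at least 2-fold so. The median was 0.997 in replicate 1 and 1.38 in replicate 2, and it stayed positive with processed values (1.34) and median centring (1.02). Camera gave adjusted p = 4.05e-33, and adjusted p = 0.336 with an estimated correlation. HIST1H4F (3.16), HIST2H4 (3.16), HIST1H2AE (1.99) and HIST1H1C (1.85) led or stood among the largest, while HIST1H3A (-1.55), HIST1H3E (-1.50) and HIST1H3J (-1.07) were lower in both replicates. None passed limma's test over all genes.

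Mitochondrially encoded genes of the respiratory chain had a median of -0.97 over 8 members (camera, adjusted p = 0.000673; adjusted p = 0.524 with an estimated correlation), and 5 were lower in both replicates. The replicate medians were -0.57 and -1.30, and MTND2, MTND4 and MTND5 had opposite signs in the replicates. The median was -0.999 with processed values and -1.16 with median centring. After MTND6, the lowest were MTND3 (-1.63), MTCO1 (-1.27) and MTCYB (-1.12), while MTND2 had -0.00. Of EGF family ligands, which activate the EGF receptor, AREG had 3.03 ± 2.36 and EREG 1.82 ± 1.44, and the median of 6 was 0.38 (adjusted p = 0.0263; adjusted p = 0.439 with an estimated correlation), or 0.58 with processed values. The KLF family had a median of 0.18 over 16 (adjusted p = 3.05e-05; adjusted p = 0.336 with an estimated correlation), led by KLF6 (3.78) and KLF2 (3.26). KLF2, KLF4, KLF6 and KLF10 are also in the immediate early list, so this rise is not separate from that list's. Of the other KLF genes, KLF5 (1.24) and KLF16 (0.63) were highest and KLF13 (-0.45) lowest. The 375 ZNF genes had 0.05 (adjusted p = 0.00312; adjusted p = 0.607 with an estimated correlation), with replicate medians of 0.09 and -0.01 and 0.09 with processed values. SAT, the enzyme that acetylates spermidine and spermine, had 4.48 ± 0.06 (adjusted p = 0.0663), and PCYOX1, which frees the prenyl group of prenylcysteines, had -1.36 ± 0.28 (adjusted p = 0.192). Large replicate differences included PTX3 (5.16 and 1.79) and PTGS2 (5.57 and 3.32), higher in replicate 1, and CDKN1C (0.59 and 2.66), higher in replicate 2.

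Heat shock genes had a higher ratio in replicate 2 for 15 of 18 members, by a median of 1.07, led by HSPA6, HSPA1L and HSPA1A. A single array or dye is argued against, since the lower array median in replicate 2 was 1.03 against a replicate 1 median of 0.09. A lower vehicle level is argued against by a median drop of 0.0936 (95% interval over genes -0.23 to 0.21), while the farnesol level was higher by 1.06. Signal shared between HSP70 copies could not carry it, since 13 members outside the HSPA family differed by 1.06 (0.31 to 1.31). A difference between the farnesol cultures stays a hypothesis, and no biological explanation was tested, as the design gives none.

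For the histone genes, a larger share of cells in S phase is argued against only weakly by the G1/S list, whose higher replicate median was -0.20 (both replicates, -0.20 and -0.46). Genes of mitosis (-0.43) and oxidative phosphorylation (-0.33) fell too, and such a wider fall could hide a rise in the G1/S list. Probes that share the signal of one transcript stay open, within a family or across families, since the lowest median of the H1, H2A, H2B and H4 families was 0.97, but its interval reached 0.16 over 5 H1 genes. This test did not take H3, which had a median of 0.76 over 12 genes, 7 higher and 3 lower in both replicates. An increase in polyadenylated histone RNA could be another candidate explanation, but it was not tested, and the primer of the amplification is not given in the sources used here.

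Over all lists but the immediate early genes, 52 of 65 members with a log2 ratio of at least 1 were larger in replicate 1, and in 6 lists grouped after the pattern was seen (ER chaperones, ER-associated degradation, UPR sensors, ATF4 and CHOP targets, MAP kinase phosphatases and NF-kappaB targets) 36 of 37 were, but 12 of 19 immediate early genes were (at least 2, 21 of 22 and 8 of 15), and in the remaining lists 12 of 28 were larger in replicate 2, heat shock genes, IFIT1, IFIT2, ADM and MYLIP among them. An equal compression of all ratios in replicate 2, as the only difference between the replicates, is argued against by those 12 of 28 members. The count cannot decide on a compression beside a larger response of those 12 in replicate 2. A compression of only some genes was not tested. The slope of replicate 2 on replicate 1 with at least 2 was 0.94 for immediate early genes (0.87 to 0.998) and 0.71 for members of the 6 lists (0.62 to 0.78). With at least 1 it was 0.93 (0.85 to 0.99) and 0.68 (0.59 to 0.75). As the 6 lists were grouped after the pattern was seen, that choice favoured their lower slope, and the gap adds no independent argument. Without saturated spots the slope was 0.92 over 13 immediate early genes (0.84 to 0.99), so saturation does not account for the slope of these genes. A higher vehicle level is argued against by a median rise of -0.0496 (-0.22 to 0.04), while the farnesol level differed by -1.28. The 36 genes larger in replicate 1 may have responded more slowly or more weakly in replicate 2, a hypothesis for which no biological explanation was tested, as the design names no such factor.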
